A study of Homo sapiens with 6 samples.

How the data were processed

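Poly(A) RNA of MOLM-13 cells was sequenced in 6 libraries, 3 from cells treated with 2 µM UC-764864 for 24 h and 3 from cells treated with DMSO. RNA was extracted with a column kit and read as 75 bp paired ends, per the labels' protocols, which also call the libraries "single stranded". The authors deposited whole-number counts of reads per gene in a table with a column per library, without normalization. FastQC 0.11.7, HISAT2 2.0.5, featureCounts 1.5.2 and the genome build GRCh37 are named, without roles or order, in the submitters' processing notes. The gene annotation release and whether counting used the strand are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and reads shared by near-identical copies can be split between them, so such genes are named as uncertain. Coordinates are not printed, because the table names genes by symbol and no GRCh37 annotation was used here.

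A deposited table gives each column its treatment and no replicate number, so libraries are called by their column names and were never paired. UDI0051, UDI0052 and UDI0053 were treated with UC-764864, and UDI0054, UDI0055 and UDI0056 with DMSO. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total counts ranged from 17073654 to 25014437 per UC-764864 library and from 16136156 to 24511499 per DMSO library. A count of 3, taken as the floor, corresponded to 0.123 to 0.198 CPM, counts scaled by library size. Reads carry no molecular identifiers, so floors cover counting error only. Pairs of libraries were compared by a chi-square of their counts over genes, which ranged from 4.73 to 86.7 per degree of freedom. No pair came down to sampling noise, so all 6 libraries were kept as separate samples.

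The column of DMSO library UDI0055 holds 0 in 2 unbroken runs of the table, 115 rows from PKDREJ to RN7SKP144 at the end of chromosome 22 and 3684 rows from RNU6-785P to CTBP2P1 that hold the X, Y and mitochondrial genes and unplaced scaffolds. Of these 3799 rows, 979 have counts in other libraries, and they take 7.73% to 9.19% of the counts there. All 399 rows of the runs with at least 50 counts in each other library are at 0, against 0 of 10202 such rows elsewhere in the table. These zeros were read as missing values. The tests therefore used the 52839 of 56638 rows that all 6 libraries hold, a decision taken after the zeros had been seen and before any test was run. The design fixed earlier would have kept every row as deposited. That setting called 22 genes higher and 125 lower, against 690 and 1097 on the rows held by all libraries.

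Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, scaled by TMM factors (0.978 to 1.03) and tested with the quasi-likelihood F test (glmQLFit and glmQLFTest) with treatment as the only term. P-values were adjusted by Benjamini-Hochberg over 13490 genes, and an adjusted p under 0.05 was the threshold. Log2 fold changes are UC-764864 over DMSO, and their standard errors (SE) were taken as the size of the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Log2 CPM values for principal components and list tests had a prior count of 2.

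Gene lists numbered 26 and held 900 symbols. They covered UBE2N partners, NF-kB targets, the TLR and IL1R pathway, the type I interferon response, p53 targets, homologous recombination and Fanconi genes, DNA replication and S phase, G2 and mitosis, monocyte and granulocyte maturation, leukaemic stem cell and KMT2A target genes, MYC targets and ribosome biogenesis, the amino acid and integrated stress response, the unfolded protein response of the ER, the heat shock response, NRF2 and oxidative stress targets, cholesterol synthesis and uptake, glycolysis and hypoxia response, oxidative phosphorylation, proteasome subunits, apoptosis regulators and MHC class II presentation. The other 5 were controls: lymphoid, erythroid and megakaryocyte, and stromal and epithelial markers, mitochondrially encoded genes and replication-dependent histones. Each of the 24 lists with at least 5 tested members was compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was an alternative, and fry gave the p for a shared direction. The treatment comparison, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

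Named genes are UBE2N, the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between groups, and members of each list in order of p. Up to 4 members were taken from a list that passed its test, 1 from a list that did not, and up to 2 from a control list. Any other gene is named with the statement that it was chosen after its values were seen. This rule took 74 genes.

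The alternatives were RLE factors, library size only, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 20 counts), DESeq2 1.42.0, limma-voom, leaving out each library, a log2 fold change of at least 1, and glmTreat against a 1.5-fold change. The fit with the zeros of UDI0055 kept as counts is that of the fixed design, and became an alternative when the rows were set aside after the zeros were seen. Chosen after the data were seen were that fit with a robust estimate of the shared spread, removal of each library's trend on GC content (a spline with 4 degrees of freedom), and the fit without UDI0052 and UDI0056. GC values came from the transcripts of GENCODE release 29, matched by symbol. They covered 86.3% of tested and 91.0% of called genes. Removing the trend also removes any treatment effect that follows GC content.

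The gene test was tested on simulated counts for this comparison, with 200 genes changed in each of 5 runs. On rows held by all libraries (13321 genes) it recovered 40.9% of changes of 1.5-fold, 84.6% of 2-fold and 97.9% of 4-fold, with 6.82% of calls false. With the zeros kept (13868 genes) these shares were 4.53%, 47.7% and 88.2%. The spread shared by genes was estimated with 30.2 prior degrees of freedom in the simulated rows held by all libraries and 7.71 in the data, so the shares do not carry over directly. The list test called 5 of 5 shifted lists and 0 of 100 unshifted lists. The simulated genes were drawn independently of each other, so the simulated lists do not give the rate of false list calls in the data. Up to 12 of 24 lists passed in a split of the libraries that mixed the treatments. Such a split keeps part of the treatment difference and does not give that rate either.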

Results

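Transcript levels were measured in MOLM-13, a human acute myeloid leukaemia line of monocytic type that carries a KMT2A-MLLT3 fusion. The series title calls UC-764864, which the series design text writes as UC-744864, an inhibitor of UBE2N, a ubiquitin-conjugating enzyme that builds signalling ubiquitin chains in innate immune pathways and in DNA damage tolerance. The comparison asks which transcripts differed after 24 h at 2 µM from those of cells given DMSO, the solvent. Libraries UDI0051, UDI0052 and UDI0053 of the UC-764864 group held 25014437, 17073654 and 21287807 counts, and UDI0054, UDI0055 and UDI0056 of the DMSO group held 23879122, 24511499 and 16136156. The first principal component held 56.2% of the variance and separated the treatments, and the second, with 20.4%, set UDI0052 and UDI0056 apart from the rest. These were also the libraries with the smallest share of counts in GC-rich genes, 13.3% and 13.0% against 15.5% to 17.5% in the others. In UDI0055, 3799 rows of the table stand at 0, among them all X-linked and mitochondrial genes, and the comparison uses the 52839 rows that every library holds.

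**Figure D1:**
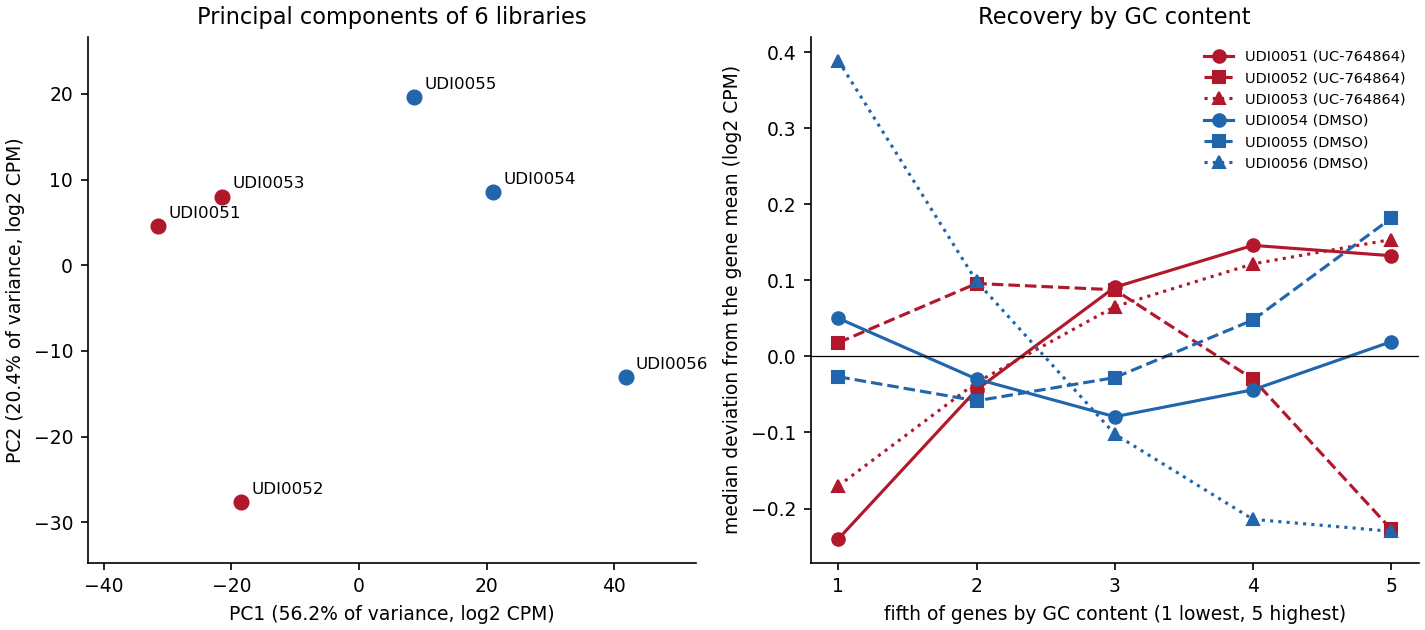
Left, the 6 libraries on the first and second principal components of log2 CPM, with UC-764864 in red and DMSO in blue; right, the median deviation of each library from the gene mean (log2 CPM) in each of 5 bins of genes by GC content. UDI0052 and UDI0056 lie lowest among genes of highest GC content, and the first component parts the treatments.

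Lists that passed as lower after UC-764864 included the type I interferon response (22 of 47 members fell), cholesterol synthesis (17 of 30), glycolysis and hypoxia (16 of 36), NF-kB targets (7 of 38) and p53 targets (6 of 32), each with adjusted p = 0.178 with an estimated correlation. Lists that passed as higher included MYC targets and ribosome biogenesis (16 of 49 members rose), DNA replication (11 of 49), the proteasome (9 of 37), heat shock (9 of 30) and NRF2 (8 of 38), with adjusted p = 0.178 with an estimated correlation, or 0.189 for DNA replication. Control lists that passed as lower in the same test were lymphoid markers (camera adjusted p = 0.0241), stromal and epithelial markers (0.0472) and replication-dependent histones (3.51e-04), with adjusted p = 0.198, 0.178 and 0.178 with an estimated correlation. HMOX1, the heme-degrading oxygenase, rose 9.05-fold, from 2.66 ± 0.287 to 24.3 ± 2.07 CPM (SD, n = 3 per group), and the interferon-induced gene IFI6 fell 5.26-fold, from 13.8 ± 1.38 to 2.59 ± 0.481 CPM. In all, 690 of 13490 genes were higher and 1097 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), and 42 and 343 of them changed by at least 2-fold. The 3 libraries of each group did not overlap for 1780 of the 1787 called genes, and for 36.1% of all tested genes, where chance gives 10%. Called genes were picked for their difference between the same libraries, so their lack of overlap is no separate support. The median log2 fold change of all genes was 0.01.

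These counts depended on single libraries and on the rows at 0. With those rows kept as counts, 22 genes were higher and 125 lower, and 24 of the 65 named genes called in the comparison still passed: HMOX1, RPS10, MMP2, IFI6, TMED7, HIST1H2AC, MSMO1, ICAM1, CCL5, IER3, OAS2, OAS1, IFI44L, LYZ, HOXA9, HSPA6, HSPA1A, NQO1, STARD4, INSIG1, BNIP3L, SLC2A3, CA9 and HLA-DRA. The other 41 then had adjusted p from 0.0525 to 0.0856. Without UDI0051, 62 genes were higher and 278 lower, without UDI0053, 166 and 460, and without UDI0054, 94 and 475. Without UDI0052 the counts were 295 and 947, and without UDI0055 they were 1525 and 1729. With library size as the only scaling, 508 genes were higher and 1271 lower, so that 28.6% of calls were rises, against 38.6% with TMM factors. With each library's GC trend removed, 1777 genes were higher and 1778 lower among 11647 genes with a GC value, against 641 and 985 of these genes in the comparison as run.

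**Figure D2:**
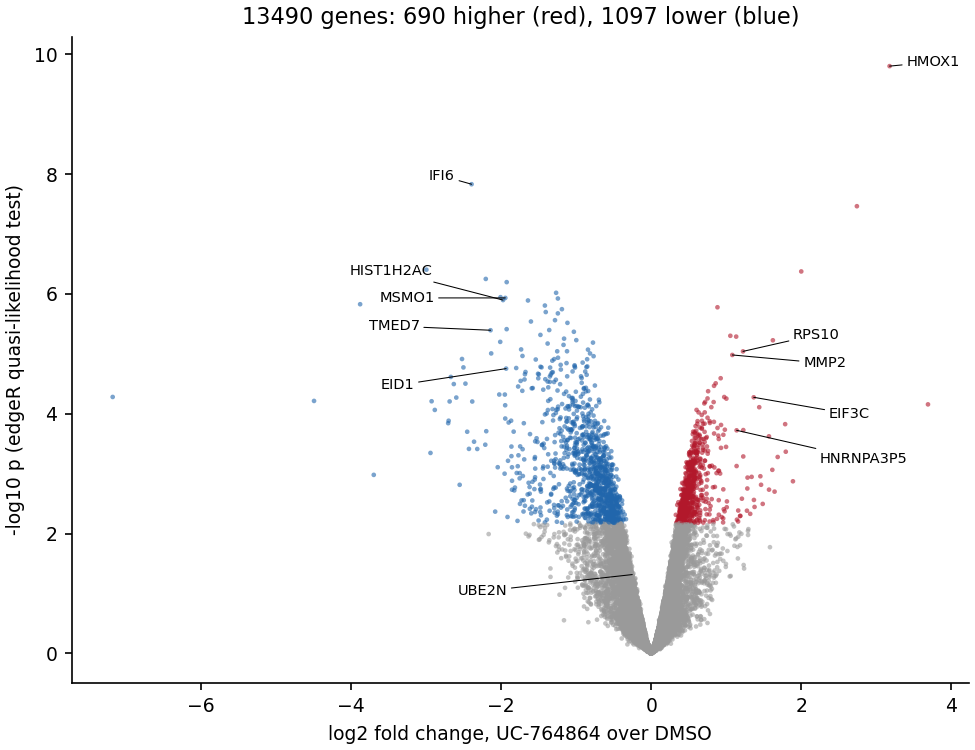
Log2 fold change of each of 13490 genes (UC-764864 over DMSO, horizontal axis) against −log10 of the unadjusted p (edgeR), with the 690 higher genes in red, the 1097 lower in blue and the others in grey. UBE2N, at −0.25, lies among the grey points, and HMOX1, at 3.18, has the smallest p.

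UBE2N itself was at 159 ± 10.9 CPM after UC-764864 and 189 ± 17.0 CPM after DMSO, a log2 fold change of −0.25 ± 0.11 (SE) that did not pass (edgeR adjusted p = 0.156). It passed only with the GC trend removed, at −0.19 (adjusted p = 0.0491). The UBE2N partner list holds ubiquitin ligases and cofactors, and also UBE2N itself, PCNA and the deubiquitinase genes CYLD, TNFAIP3 and OTUB1. Of its 23 tested members, 2 fell and 0 rose (1 and 0 adjusted over the list alone), a share of falls close to that of all genes tested (1097 of 13490). BIRC2, a ubiquitin ligase of TNF receptor signalling, fell by 0.73 ± 0.16 on the log2 scale (adjusted p = 0.0174), and UBE2V2, chosen after its values were seen, fell by 0.49 (adjusted p = 0.0499). The BIRC2 call was lost without UDI0051 (adjusted p = 0.083) and without UDI0053 (adjusted p = 0.0623). The list as a whole did not pass (camera adjusted p = 0.701; adjusted p = 0.772 with an estimated correlation), and its median of 0.07 and mean of −0.02 differed in sign, the test direction being higher.

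Under the naming rule, which asks for a mean of at least 5 CPM over all 6 libraries, the largest rises beyond HMOX1 were those of EIF3C, RPS10, HNRNPA3P5 and MMP2. HSPA6, HSPA1A and CLU, the last chosen after its values were seen, rose more than EIF3C (2.00, 1.62 and 2.74 on the log2 scale) but missed that mean. MMP2, a secreted gelatinase, rose 2.12-fold, from 6.71 ± 1.03 to 14.3 ± 0.0803 CPM (adjusted p = 0.0032). EIF3C, a translation initiation factor subunit, had a log2 fold change of 1.37 ± 0.22, RPS10, a ribosomal protein gene, 1.22 ± 0.16, and the pseudogene HNRNPA3P5 1.14 ± 0.21, with adjusted p of 0.00586, 0.00299 and 0.00976. These 3 values are uncertain, because EIF3C has the near-identical copy EIF3CL, RPS10 overlaps a readthrough gene and HNRNPA3P5 is a copy of HNRNPA3. By the same rule, the largest falls were those of IFI6, TMED7, HIST1H2AC, MSMO1 and EID1. IFI44L (−3.88 ± 0.44, edgeR adjusted p = 0.0014) and CA9 (−2.48 ± 0.38, adjusted p = 0.0045) fell more than IFI6 but missed the mean of 5 CPM. After UC-764864 they stood at 0.177 ± 0.0183 and 0.28 ± 0.13 CPM, near the floor of 0.123 to 0.198 CPM. OAS2 at −2.21 and OAS1 at −2.01 also missed that mean. TMED7, a cargo receptor of early secretory transport whose locus also holds a readthrough gene, went from 64.3 ± 28.1 to 14.6 ± 2.7 CPM (−2.14 ± 0.27, adjusted p = 0.00218). EID1, an inhibitor of histone acetyltransferases, went from 73.4 ± 31.6 to 19.2 ± 5.22 CPM (−1.93 ± 0.28, adjusted p = 0.0036).

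Interferon-stimulated genes, which encode antiviral effectors and their regulators, made up the group with the smallest p. Of 47 tested, 22 fell and 0 rose (27 and 1 adjusted over the list alone), with a median log2 fold change of −0.59. The list test gave a camera adjusted p of 9.61e-14, and adjusted p = 0.178 with an estimated correlation. IFI6 fell by 2.40 ± 0.18 on the log2 scale (adjusted p = 9.94e-05). OAS2 and OAS1, synthetases activated by viral RNA, fell from 3.78 ± 0.372 to 0.827 ± 0.129 CPM and from 5.83 ± 0.662 to 1.47 ± 0.416 CPM, with log2 fold changes of −2.21 ± 0.23 and −2.01 ± 0.22 (adjusted p = 0.00122 and 0.00133). All 3 calls held in each fit without a library.

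NF-kB targets fell as a list, with 7 of 38 members lower and 0 higher (11 and 1 adjusted over the list alone) and a median of −0.19. Its camera adjusted p was 0.00777, with adjusted p = 0.178 with an estimated correlation. The adhesion molecule ICAM1 fell 2.04-fold (−1.03 ± 0.13, adjusted p = 0.00222), and the chemokine CCL5 fell from 177 ± 20.0 to 97.9 ± 6.71 CPM (−0.85 ± 0.12, adjusted p = 0.00357). IER3, an immediate early gene, and BCL3, an atypical IkB protein, had log2 fold changes of −0.91 ± 0.15 and −0.88 ± 0.17 (adjusted p = 0.00545 and 0.0116). The TLR and IL1R pathway list holds receptor and adaptor genes, and also kinases such as MAPK8 and transcription factors such as IRF7. Of its 28 tested members 2 fell and 0 rose, the same counts when adjusted over the list alone. This share of falls was close to that of all genes tested (1097 of 13490). That list had a median of −0.07 and passed narrowly (camera adjusted p = 0.0472; adjusted p = 0.178 with an estimated correlation). TLR1 and TLR6, receptors that pair with TLR2 to bind bacterial lipoproteins, fell by 0.90 ± 0.17 and 0.71 ± 0.15 (adjusted p = 0.0109 and 0.016). TLR4, at −0.44 ± 0.15, and MAPK8, at −0.42 ± 0.15, did not pass (adjusted p = 0.0746 and 0.0789). TLR4 passed without UDI0052 (adjusted p = 0.03), without UDI0052 and UDI0056 (0.0156) and with no filter (0.043), and MAPK8 without UDI0055 (0.0383) and with no filter (0.0342). The list missed the threshold with the GC trend removed (adjusted p = 0.0506, median −0.09) and without UDI0052, UDI0053, UDI0055 or UDI0056 (adjusted p = 0.118, 0.0722, 0.132 and 0.0967). TLR1 was lost without UDI0051 (adjusted p = 0.053), and TLR6 without UDI0051, UDI0053 or UDI0054 (adjusted p = 0.0932, 0.0514 and 0.0512).

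Genes of the cholesterol synthesis and uptake list, which also holds fatty acid synthesis genes such as FASN and SCD, fell broadly. Of 30 tested, 17 fell and 0 rose (18 and 1 adjusted over the list alone), with a median of −0.47 (camera adjusted p = 4.41e-08; adjusted p = 0.178 with an estimated correlation). Of 2 enzymes of the late sterol pathway, MSMO1 fell 3.85-fold from 112 ± 32.2 CPM and SC5D went from 69.8 ± 22.6 to 25.1 ± 4.1 CPM (−1.95 ± 0.21 and −1.48 ± 0.21, adjusted p = 0.00133 and 0.00357). STARD4, an intracellular sterol carrier, fell 3.33-fold (−1.73 ± 0.23), and INSIG1, the sterol-responsive regulator of SREBP processing, fell 2.18-fold (−1.12 ± 0.15), both with an adjusted p of 0.00299. These 4 calls held in each fit without a library. In the glycolysis and hypoxia list, 16 of 36 fell and 1 rose (17 and 2 adjusted over the list alone), with a median of −0.23 (camera adjusted p = 3.51e-04; adjusted p = 0.178 with an estimated correlation). The member that rose, chosen after its values were seen, was the hexokinase HK1 at 0.47. BNIP3L, a mitophagy receptor, fell from 215 ± 49.4 to 87.6 ± 16.5 CPM (−1.29 ± 0.18, adjusted p = 0.00328). The glucose transporter SLC2A3 fell 2.31-fold (adjusted p = 0.00357), and EGLN1, the oxygen-sensing prolyl hydroxylase, fell by 0.77 ± 0.13 (adjusted p = 0.0078).

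Targets of p53 fell, with 6 of 32 lower and 0 higher (12 and 1 adjusted over the list alone) and a median of −0.23 (camera adjusted p = 0.02; adjusted p = 0.178 with an estimated correlation). The cyclin gene CCNG1 fell from 225 ± 49.4 to 115 ± 15.9 CPM (−0.96 ± 0.16, adjusted p = 0.00647), and TP53INP1, a stress-induced autophagy regulator, fell by 1.02 ± 0.19 (adjusted p = 0.00869). FAS, the death receptor, and BBC3, which encodes the pro-apoptotic protein PUMA, had log2 fold changes of −0.69 ± 0.15 and −0.72 ± 0.17 (adjusted p = 0.0153 and 0.019). FAS was lost without UDI0051, UDI0053 or UDI0054 (adjusted p = 0.083, 0.0502 and 0.0531), and BBC3 without UDI0051 or UDI0054 (adjusted p = 0.0584 and 0.0733). Apoptosis regulators as a list did not pass (camera adjusted p = 0.491; adjusted p = 0.535 with an estimated correlation). Of its 38 members 5 fell and 1 rose (8 and 1 adjusted over the list alone), and its median of 0.01 lay on the other side of 0 from its mean of −0.13 and from the test direction. Besides FAS, BIRC2 and BBC3, the members that fell were BCL2A1 at −1.36 and MCL1 at −0.43, both anti-apoptotic BCL2 relatives, and the member that rose was DIABLO, an antagonist of apoptosis inhibitors, at 0.64; these were chosen after their values were seen.

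MHC class II genes fell as a list, though only 1 of 12 passed alone and 0 rose (4 and 1 adjusted over the list alone), with a median of −0.29 (camera adjusted p = 0.0318; adjusted p = 0.178 with an estimated correlation). The share of 1 in 12 was close to that of falls among all genes tested (1097 of 13490). HLA-DRA, an antigen-presenting chain, fell 2.28-fold, from 20.0 ± 1.85 to 8.76 ± 0.573 CPM (adjusted p = 0.00142). HLA-DRB1 at −0.88 ± 0.28, HLA-DQB1 at −0.58 ± 0.20 and the transcription factor gene RFX5 at 0.36 ± 0.12 did not pass (adjusted p = 0.0555, 0.071 and 0.0628). HLA-DRB1 passed without UDI0056 (adjusted p = 0.00909), without UDI0052 and UDI0056 (0.0242), with RLE factors (0.0478), library size only (0.0457), no filter (0.00364) and the GC trend removed (0.00657). HLA-DQB1 passed without UDI0056 (adjusted p = 0.0399) and with the GC trend removed (0.0191), and RFX5 without UDI0055 (0.0301), with DESeq2 (0.0436) and with the GC trend removed (0.0485). The list missed the threshold without UDI0052 (adjusted p = 0.0976) and without UDI0055 (adjusted p = 0.111).

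**Figure D3:**
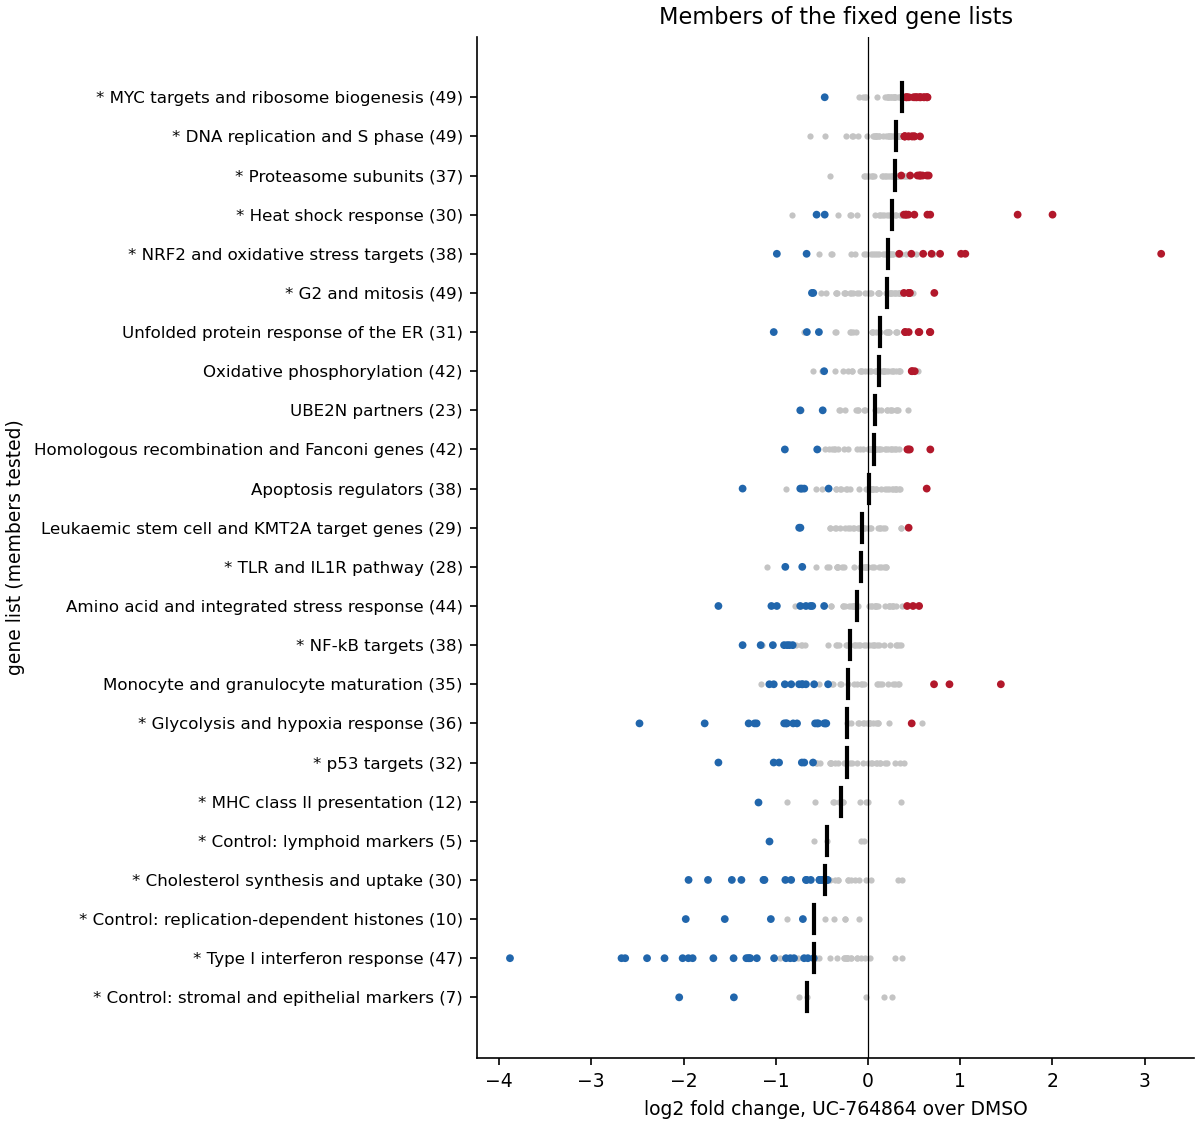
Log2 fold change (UC-764864 over DMSO) of the tested members of 24 gene lists, with called rises in red, called falls in blue, other members in grey and a black bar at each median; a star marks the 16 lists that passed the camera test with a preset correlation. Medians run from −0.66 to 0.37, and none of the 16 passed with an estimated correlation.

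MYC targets and ribosome biogenesis genes rose, with 16 of 49 higher and 1 lower (34 and 1 adjusted over the list alone) and a median of 0.37 (camera adjusted p = 1.01e-09; adjusted p = 0.178 with an estimated correlation). NCL, the nucleolar protein nucleolin, went from 1694 ± 101 to 2576 ± 198 CPM (0.60 ± 0.10, adjusted p = 0.00678). LYAR, a nucleolar growth regulator, NOP56, a snoRNP core protein, and TSR1, a factor of small subunit assembly, rose by 0.63 ± 0.13, 0.57 ± 0.12 and 0.53 ± 0.11 (adjusted p = 0.0123, 0.0127 and 0.0154). LYAR, NOP56 and TSR1 were lost without UDI0054 (adjusted p = 0.0596, 0.0509 and 0.0733), and NOP56 and TSR1 also without UDI0051 (adjusted p = 0.0665 and 0.0824). The member that fell was HSPE1 at −0.47, a mitochondrial co-chaperonin that the heat shock list also holds, chosen after its values were seen. Proteasome subunit genes rose in 9 of 37 cases and fell in 0 (19 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 2.21e-06; adjusted p = 0.178 with an estimated correlation). PSME3, an activator subunit, rose by 0.59 ± 0.13, the base ATPase gene PSMC5 by 0.64 ± 0.15, and the regulatory particle genes PSMD1 and PSMD2 by 0.56 ± 0.12 and 0.57 ± 0.14, with adjusted p from 0.0153 to 0.0209. All 4 were lost without UDI0051 (adjusted p from 0.0781 to 0.0991) and without UDI0054 (adjusted p from 0.0747 to 0.0906). PSMD1 was also lost without UDI0052 (adjusted p = 0.0513) and PSMD2 without UDI0053 (adjusted p = 0.0625).

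Genes of DNA replication and S phase rose by small amounts, 11 of 49 higher and 0 lower (23 and 2 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 2.78e-06; adjusted p = 0.189 with an estimated correlation). CHAF1A and CHAF1B, subunits of the chromatin assembly factor, rose 1.48-fold and 1.39-fold (adjusted p = 0.0256 and 0.0212). The initiation factor gene MCM10 rose from 65.1 ± 5.45 to 92.2 ± 7.93 CPM and the clamp loader gene RFC2 from 56.9 ± 4.35 to 77.5 ± 3.85 CPM (adjusted p = 0.0215 and 0.0281). Each of the 4 was lost without UDI0051, UDI0053 or UDI0054 (adjusted p from 0.0512 to 0.163), and CHAF1B, MCM10 and RFC2 also without UDI0052 (adjusted p = 0.0616, 0.0681 and 0.0584). The G2 and mitosis list passed with a median of 0.20, 5 of 49 higher and 2 lower (15 and 4 adjusted over the list alone), at a camera adjusted p of 0.0241 and adjusted p = 0.453 with an estimated correlation. MKI67, the proliferation marker, rose from 238 ± 26.4 to 391 ± 29.6 CPM (adjusted p = 0.00616). The spindle genes KIF23 and AURKA rose by 0.45 ± 0.11 and 0.44 ± 0.11 (adjusted p = 0.026 and 0.0287), and ASPM, a spindle pole gene, fell by 0.61 ± 0.14 (adjusted p = 0.0214). Chosen after their values were seen, the remaining called members were TPX2 at 0.44, KIF20A at 0.39 and the checkpoint gene MAD2L1 at −0.59. KIF23, AURKA and ASPM were lost without UDI0051, UDI0053 or UDI0054 (adjusted p from 0.0605 to 0.142), and KIF23 and AURKA also without UDI0052 (adjusted p = 0.0863 and 0.0775). The mitotic list missed the threshold without UDI0052 (adjusted p = 0.166) and without UDI0054 (adjusted p = 0.0915). Homologous recombination and Fanconi genes did not pass (median 0.07, camera adjusted p = 0.333; adjusted p = 0.647 with an estimated correlation), with 4 of 42 higher and 2 lower, the same counts when adjusted over the list alone. MDC1, a scaffold at DNA breaks, rose by 0.68 ± 0.12 (adjusted p = 0.00934), a call lost without UDI0051 (adjusted p = 0.0526). The others, chosen after their values were seen, were TP53BP1 at 0.45, UIMC1 at 0.44, EXO1 at 0.43, FAM175A at −0.90 and FANCF at −0.55.

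The NRF2 and oxidative stress list rose, with 8 of 38 higher and 2 lower (13 and 2 adjusted over the list alone) and a median of 0.22 (camera adjusted p = 9.20e-04; adjusted p = 0.178 with an estimated correlation). With the GC trend removed its median was 0.09 (adjusted p = 0.00606). HMOX1 rose by 3.18 ± 0.16 (adjusted p = 2.12e-06) and NQO1, a quinone reductase, by 1.06 ± 0.13, from 10.6 ± 0.834 to 21.9 ± 1.68 CPM (adjusted p = 0.00239). FTL, the ferritin light chain, rose 1.51-fold (adjusted p = 0.0133), a call lost without UDI0051 (adjusted p = 0.0543) and without UDI0053 (adjusted p = 0.0514). SLC7A11, the cystine transporter, fell by 0.99 ± 0.20 (adjusted p = 0.0116), and so did the biliverdin reductase gene BLVRB, at −0.67, chosen after its values were seen. In the heat shock list, 9 of 30 rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.00164; adjusted p = 0.178 with an estimated correlation). HSPA6, a strictly inducible chaperone, rose from 1.33 ± 0.2 to 5.4 ± 0.5 CPM (2.00 ± 0.20, adjusted p = 0.00114), and HSPA1A by 1.62 ± 0.21 (adjusted p = 0.0025). The HSPA1A value is uncertain because the gene may share reads with HSPA1B, and that sharing was not measured. HSPA1B was itself tested and was not called. AHSA1 and STIP1, cochaperones of HSP90, rose by 0.67 ± 0.13 and 0.64 ± 0.13 (adjusted p = 0.00952 and 0.0117). AHSA1 was lost without UDI0051 (adjusted p = 0.0521), and STIP1 without UDI0051 or UDI0054 (adjusted p = 0.0621 and 0.0572). The members that fell, chosen after their values were seen, were PTGES3 at −0.56 and HSPE1 at −0.47.

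**Figure D4:**
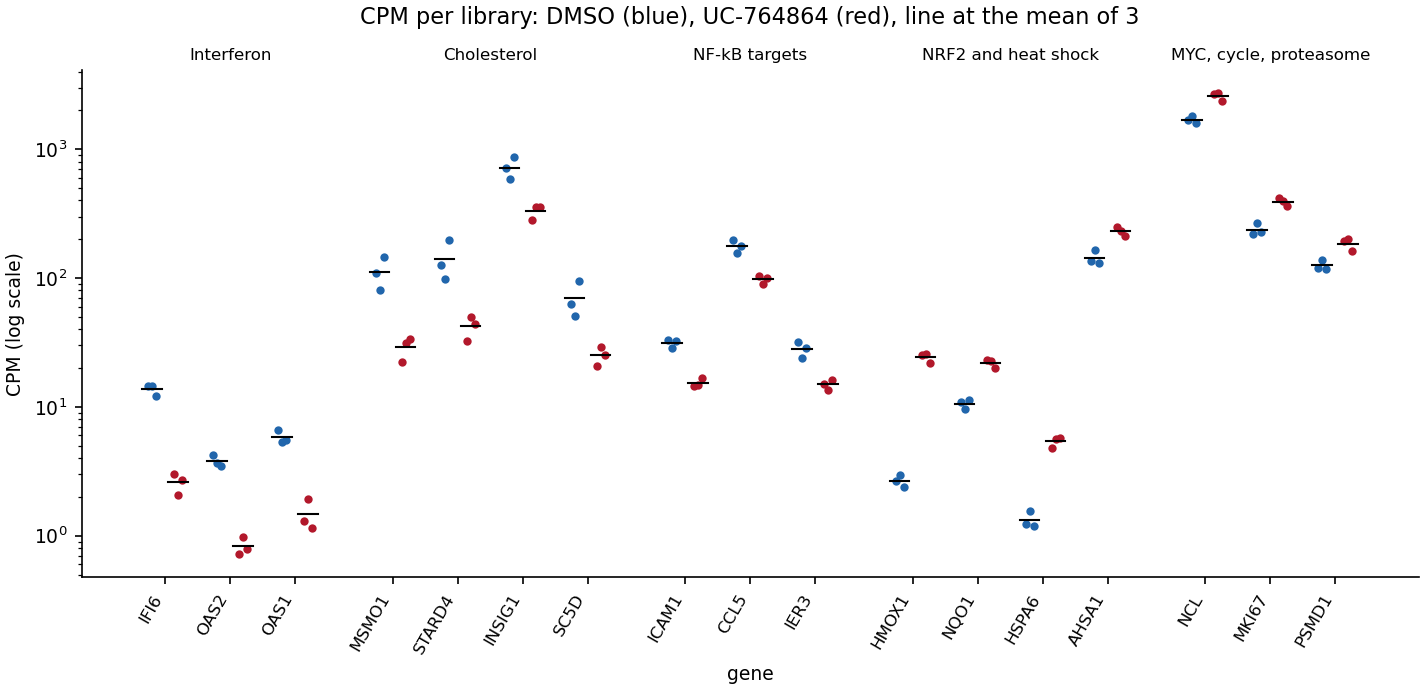
CPM per library on a log axis for genes of the interferon, cholesterol, NF-kB, NRF2, heat shock, MYC, mitosis and proteasome lists, DMSO in blue, UC-764864 in red, with a line at the mean of 3 libraries. The groups did not overlap for any of these genes, as for HMOX1 (2.66 CPM after DMSO and 24.3 CPM after UC-764864). The genes were picked by their p in the same libraries.

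Further stress and metabolic lists did not pass. In the unfolded protein response of the ER, 7 of 31 rose and 3 fell, the same counts when adjusted over the list alone (median 0.13, camera adjusted p = 0.157; adjusted p = 0.556 with an estimated correlation). CALR, the ER chaperone calreticulin, rose from 1998 ± 298 to 3191 ± 218 CPM (adjusted p = 0.0086), while DNAJB9 at −1.02, ERO1L at −0.66 and DERL3 at −0.53 fell and were chosen after their values were seen. The amino acid and integrated stress response list had 8 of 44 lower and 3 higher (11 and 4 adjusted over the list alone), a median of −0.12 and a camera adjusted p of 0.158 (adjusted p = 0.306 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, fell by 1.05 ± 0.17 (adjusted p = 0.00588), and the 3 that rose, chosen after their values were seen, were the tRNA synthetase genes YARS at 0.55, MARS at 0.49 and GARS at 0.42. For oxidative phosphorylation, 3 of 42 rose and 1 fell, the same when adjusted over the list alone (median 0.11, camera adjusted p = 0.0602; adjusted p = 0.189 with an estimated correlation). NDUFB9, a complex I subunit, rose by 0.48 ± 0.12 (adjusted p = 0.0223), but not past the threshold without UDI0051, UDI0052, UDI0053 or UDI0054 (adjusted p = 0.111, 0.0584, 0.0684 and 0.0692). NDUFB10 at 0.51 and NDUFA8 at 0.47 also rose and SDHD fell, at −0.48, all chosen after their values were seen.

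Markers of cell state moved both ways. In the monocyte and granulocyte maturation list, 10 of 35 fell and 3 rose (15 and 5 adjusted over the list alone), with a median of −0.22 that did not pass (camera adjusted p = 0.0518; adjusted p = 0.178 with an estimated correlation). LYZ, the lysozyme gene, rose from 3170 ± 120 to 5848 ± 503 CPM (0.88 ± 0.10, adjusted p = 0.00141). VCAN, a matrix proteoglycan, and CLEC12A, a myeloid lectin receptor, rose too, at 1.44 and 0.72, and were chosen after their values were seen. Those that fell, also chosen after their values were seen, included ITGAX at −1.07, ITGAM at −1.02, LILRB2 at −0.90, CD36 at −0.83, CEBPD at −0.72, CD86 at −0.71, CEBPB at −0.67, CSF1R at −0.58 and TYROBP at −0.43. The list passed without UDI0051 (adjusted p = 0.042). Leukaemic stem cell and KMT2A target genes did not pass (median −0.07, camera adjusted p = 0.217; adjusted p = 0.557 with an estimated correlation), with 2 of 29 lower and 1 higher (5 and 2 adjusted over the list alone). HOXA9, a homeobox gene driven by KMT2A fusions, fell from 107 ± 7.82 to 64.2 ± 7.2 CPM (−0.73 ± 0.12, adjusted p = 0.00647). HOXA3 fell as well, at −0.75, and MYC rose, at 0.44, both chosen after their values were seen.

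Control lists were tested in the same way, and each one with at least 5 tested members passed as lower. A pass with the preset correlation was therefore not particular to the pathway lists. Lymphoid markers fell, with 1 of 5 lower and 0 higher (2 and 0 adjusted over the list alone), a median of −0.45 and a camera adjusted p of 0.0241 (adjusted p = 0.198 with an estimated correlation). CD3D, a T cell receptor subunit, went from 1.09 ± 0.132 to 0.507 ± 0.047 CPM (adjusted p = 0.0358), and NKG7, a granule protein gene at 51.5 ± 4.12 CPM after DMSO, did not pass (−0.45 ± 0.14, adjusted p = 0.0548). CD3D passed in a single leave-one-out fit, that without UDI0055 (adjusted p = 0.0274), and was otherwise at 0.0843 to 0.141. It was also lost with DESeq2 (adjusted p = 0.114), with rows at 0 kept (0.0619) and without UDI0052 and UDI0056 (0.111). NKG7 passed without UDI0056 (adjusted p = 0.0224), without UDI0052 and UDI0056 (0.0238), with RLE factors (0.0424), library size only (0.0359), no filter (0.0193), the stricter filter (0.0426), DESeq2 (0.0188) and the GC trend removed (7.16e-04). Without UDI0052 the lymphoid list missed the threshold (adjusted p = 0.132). Stromal and epithelial markers fell, with 2 of 7 lower and 0 higher (3 and 0 adjusted over the list alone) and a median of −0.66 (camera adjusted p = 0.0472; adjusted p = 0.178 with an estimated correlation). The growth factor receptor gene PDGFRB stood at 1.55 ± 0.281 and 0.554 ± 0.0914 CPM after DMSO and UC-764864 (adjusted p = 0.0122), and VWF, at 1.21 ± 0.382 and 0.267 ± 0.183 CPM, passed as well (adjusted p = 0.0172). In UDI0052 VWF stood at 0.0647 CPM, under the floor of 0.194 CPM of that library. VWF was lost without UDI0051 (adjusted p = 0.0553) and without UDI0054 (adjusted p = 0.0615), and the list without UDI0052, UDI0054 or UDI0055 (adjusted p = 0.0948, 0.0646 and 0.111). It also missed the threshold with the GC trend removed (adjusted p = 0.0656, median −0.78). Replication-dependent histone genes, whose transcripts lack poly(A) tails when normally processed, fell, with 4 of 10 lower and 0 higher (5 and 0 adjusted over the list alone), a median of −0.58 and a camera adjusted p of 3.51e-04 (adjusted p = 0.178 with an estimated correlation). HIST1H2AC went from 22.5 ± 5.49 to 5.7 ± 1.41 CPM (adjusted p = 0.00133), and HIST2H2BE fell by 1.05 ± 0.23 (adjusted p = 0.0163), a call lost without UDI0051, UDI0053 or UDI0054 (adjusted p = 0.0817, 0.0522 and 0.0727). HIST1H3D at −1.55 and HIST1H1C at −0.71, chosen after their values were seen, fell too. Of the erythroid and megakaryocyte markers only TFRC and EPOR were tested, and neither passed (adjusted p = 0.429 and 0.506). All 13 mitochondrially encoded mRNAs lie in the rows at 0 in UDI0055 and were not tested in this comparison.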

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

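The fit without UDI0055, the tests of its rows at 0, the test of each list that fell by itself, and the tests of the integrated stress response and of HMOX1 with the GC trend removed were chosen only after the results were seen.

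Genes in the rows at 0 in UDI0055 lay outside the comparison, and they were tested in a fit of the other 5 libraries (3 after UC-764864, 2 after DMSO; edgeR). Of 551 such genes tested, 61 were higher and 84 lower after UC-764864, in a fit that called 1401 higher and 1974 lower of 14186 genes in all, against 690 and 1097 of 13490 with UDI0055 on the rows it holds. Among the mitochondrially encoded mRNAs, which specify subunits of the respiratory chain, 11 of 13 were higher and 0 lower, with a median log2 fold change of 0.54. MT-ATP8 rose by 0.93 ± 0.13 (SE), MT-CYB by 0.67 ± 0.11, MT-ND1 by 0.65 ± 0.10 and MT-CO2 by 0.63 ± 0.10 (adjusted p = 0.00126, 0.00181, 0.00158 and 0.00229). MT-ND6 at 0.43 and MT-ND3 at −0.28 did not pass (adjusted p = 0.0745 and 0.128), nor did the mitochondrial ribosomal RNAs MT-RNR1 at 0.04 and MT-RNR2 at −0.02 (adjusted p = 0.82 and 0.891). Other non-coding transcripts in these rows moved both ways: the mitochondrial tRNAs MT-TT at −1.28 and MT-TP at −1.03 fell, MT-TM at 1.18 and MT-TL1 at 0.48 rose, and the nuclear-encoded ribosomal RNA RNA28S5 fell from 3449 to 2221 CPM (adjusted p = 7.42e-04, 0.0292, 0.0182, 0.0336 and 0.0361). A change in poly(A) selection was not tested. Mitochondrial mRNAs took 5.26%, 5.17% and 4.52% of the counts in the UC-764864 libraries and 3.59% and 3.67% in the DMSO libraries UDI0054 and UDI0056. Among X-linked genes, named after their values were seen, the pirin gene PIR rose by 1.42 and the pseudouridine synthase gene DKC1 by 0.54. AP1S2, an adaptor subunit, SLC6A8, the creatine transporter, and NXT2, an RNA export factor, had log2 fold changes of −1.59, −1.46 and −1.36. Groups of 3 libraries are too small for a check of single libraries far from the others.

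The rows at 0 in UDI0055 form 2 unbroken stretches of the table, and the candidate explanations are a loss of data and a loss of transcripts. A lack of X-linked and mitochondrial transcripts in these cells is argued against by 61 rows of the first stretch that hold counts in other libraries and are at 0 as well. By symbol, 41 of them were matched to chromosome 22 and 20 to no chromosome. The test asked for 50 rows of chromosome 22, which is met only with the unmatched rows counted. Alignments cut off before counting could give the pattern, since outside the stretches 0 of 10202 rows with at least 50 counts in each other library are at 0. That all 399 such rows inside are at 0 follows from how the stretches were picked. With these zeros kept, 147 genes were called instead of 1787, which may reflect a less certain estimate of the spread shared by genes (prior degrees of freedom 2.82 against 7.71), since a robust estimate of that spread called 1152. The step at which the counts went missing stays open.

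Fold changes followed GC content across genes (Spearman 0.25, genes not being independent replicates), with medians of −0.27, 0.00, 0.15, 0.14 and 0.02 from the lowest to the highest of 5 bins by GC content, so GC-dependent recovery might account for the lists. With each library's trend removed, the lists that rose had an adjusted p of 1.20e-09 (MYC), 3.31e-07 (proteasome), 1.81e-05 (DNA replication), 5.22e-04 (G2 and mitosis) and 9.63e-04 (heat shock) at more than 0.5 of their medians, which argues against the trend as their whole cause. Of the lists that fell, 8 of 10 kept an adjusted p under 0.05: 3.37e-14 (interferon), 3.46e-10 (cholesterol), 1.14e-05 (glycolysis and hypoxia), 6.58e-04 (histones), 9.63e-04 (p53), 0.00612 (MHC class II) and 0.00588 (both NF-kB targets and lymphoid markers). The NRF2 list stayed under 0.05 at 0.00606 with its median down from 0.22 to 0.09, and the TLR and IL1R pathway (0.0506, median −0.07 before and −0.09 after; 0.0346 to 0.132 without single libraries) and stromal markers (0.0656, median −0.66 before and −0.78 after; 0.0255 to 0.111 without single libraries) ended just above 0.05 without smaller medians, so the trend stays open for these 3. A treatment effect that follows GC content is removed with the trend and also stays open. These list tests used the preset correlation. With it, up to 12 of 24 lists passed in a split that mixed the treatments but kept part of their difference. With an estimated correlation 0 lists passed in the comparison as run, and that setting was not run with the trend removed.

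HMOX1 had the largest rise under the naming rule, with its mean of at least 5 CPM over all 6 libraries. A candidate explanation is that HMOX1 belongs to a wider stress response to UC-764864. Median log2 fold changes of the 5 GC bins lay between −0.27 and 0.15, so a GC trend of this size is too small to give the rise of HMOX1. Its removal could therefore change little, and left HMOX1 at a log2 fold change of 3.11, against 3.18 before. Without HMOX1 the NRF2 list still passed (37 members, 7 higher and 2 lower, median 0.22, camera adjusted p = 0.00361), and without HSPA6, HSPA1A and HSPA1B so did the heat shock list (27 members, 7 higher and 2 lower, median 0.23, adjusted p = 0.0215). Both leave a shared oxidative or proteotoxic response as a hypothesis, although neither full list passed with an estimated correlation (adjusted p = 0.178). Neither shortened list was run with the GC trend removed, and that trend stays open for the full NRF2 list. With the preset correlation, up to 12 of 24 lists also passed in a split that mixed the treatments but kept part of their difference. The integrated stress list had a median of −0.12. A bootstrap interval of −0.21 to 0.08 resampled its 44 member genes and not libraries, so it holds no spread between samples. The list was lower by fry (adjusted p = 0.0346) and with the GC trend removed (camera adjusted p = 0.0187, median −0.18), but not by camera as run (adjusted p = 0.158). A shared rise of this list was not seen, and its part stays open.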

How the results depend on the processing

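No paired analysis was possible because the columns carry no replicate number, so the replicate block that had been planned was not run. The setting with rows at 0 kept is that of the fixed design, which was left after the zeros were seen. The settings with a robust spread, with the GC trend removed and without UDI0052 and UDI0056 were chosen after the data were seen. No list test or named gene reversed direction in any alternative, and 0 genes were called in opposite directions in an alternative and in the comparison. The median of the apoptosis list went from 0.01 to −0.08 with the GC trend removed, and that of all genes from 0.01 to −0.03 with library size only. Among alternatives for the lists, 308 left the call as it was, 43 lost it and 7 gained it, and for the named genes these numbers were 967, 115 and 25. Leaving out a library lost calls for 27 of the 65 named genes called, and the other 38 passed in all 6 such fits.

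The number of genes higher and lower was 606 and 1161 with RLE factors, 547 and 1102 with the stricter filter, 899 and 1304 with DESeq2, 706 and 1013 with limma-voom and 559 and 1233 without UDI0052 and UDI0056. It was 827 and 1676 with no filter, where 24326 genes were tested, and 508 and 1271 with library size only. It fell to 42 and 343 with a log2 fold change of at least 1 and to 7 and 72 with glmTreat, as these ask for larger changes, and rose to 1777 and 1778 with the GC trend removed, where the cause was not tested. Rows at 0 kept gave 22 and 125, all 147 shared with the calls of the comparison, and 327 and 825 with a robust spread. Leaving out a library gave 62 to 1525 higher genes and 278 to 1729 lower genes: 62 and 278 without UDI0051, 295 and 947 without UDI0052, 166 and 460 without UDI0053, 94 and 475 without UDI0054, 1525 and 1729 without UDI0055 and 512 and 912 without UDI0056. Each of these fits drops 1 library, so sample number alone does not account for the range, and the causes of the losses and of the gain without UDI0055, which shared 1731 calls, were not tested.

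With an estimated inter-gene correlation every one of the 16 lists missed the threshold. The camera adjusted p was then 0.453 for G2 and mitosis, 0.198 for lymphoid markers, 0.189 for DNA replication and 0.178 for the other 13. In that setting 2 lists had an unadjusted camera p under 0.05, the type I interferon response (0.0161) and cholesterol synthesis (0.0362). The shared 0.178 comes from the Benjamini-Hochberg adjustment, and the unadjusted p of these 13 lists reached 0.104 (MYC targets). What made the lists miss the threshold was not tested. By fry, 18 of 24 lists passed, while G2 and mitosis did not (adjusted p = 0.111). For the TLR and IL1R pathway the adjusted p was 0.0914 with no filter, 0.0543 with the stricter filter, 0.0959 with rows at 0 kept, 0.0506 with the GC trend removed, 0.115 without UDI0052 and UDI0056, and 0.0346 to 0.132 without single libraries. Stromal markers were at 0.0548 with library size only, 0.0724 with no filter, 0.0612 with limma-voom, 0.0558 with rows at 0 kept, 0.0656 with the GC trend removed, 0.0727 without UDI0052 and UDI0056, and 0.0255 to 0.111 without single libraries. Lymphoid markers were at 0.0612 with limma-voom, 0.105 without UDI0052 and UDI0056 and 0.0143 to 0.132 without single libraries, MHC class II at 0.084 and 0.0184 to 0.111, and G2 and mitosis at 0.102 and 0.00432 to 0.166 in the latter settings. Lists that gained the threshold were homologous recombination (0.0287) and the integrated stress response (lower, 0.0187) with the GC trend removed, monocyte maturation with limma-voom (0.0437), with the GC trend removed (0.0331) and without UDI0051 (range 0.042 to 0.152 without single libraries), and oxidative phosphorylation with no filter (0.0411) and limma-voom (0.0483). The cause of these changes was not tested. Depth limits the precision of genes near 0.198 CPM, the floor of the shallowest library.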

Other observations

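The genes of the first paragraph were chosen after their values were seen; the counts over other splits of the libraries were planned.

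The 12 genes below lie outside the fixed lists and were called in the comparison (edgeR, adjusted over all genes), and no test was made of what they share. BMI1, a Polycomb group gene whose locus also holds a readthrough gene, fell from 328 ± 106 to 86.3 ± 10.2 CPM (SD, n = 3 per group; log2 fold change −1.93, adjusted p = 0.00122). SUCNR1, the succinate receptor, fell by 1.93 ± 0.24 (SE), the receptor tyrosine kinase gene AXL by 1.41 ± 0.16 and the interleukin receptor gene IL2RA by 1.41 ± 0.21 (adjusted p = 0.00218, 0.0015 and 0.00418). JUN, an AP-1 transcription factor gene, went from 41.9 ± 3.58 to 19.3 ± 2.36 CPM (adjusted p = 0.00186). MIR155HG, the host transcript of miR-155, fell by 1.79 ± 0.41 (adjusted p = 0.0187), a call lost without UDI0051 (adjusted p = 0.0543) and without UDI0053 (adjusted p = 0.0514). CLU, which encodes the extracellular chaperone clusterin, rose from 1.26 ± 0.39 to 8.7 ± 0.918 CPM (2.74 ± 0.22, adjusted p = 1.54e-04). The replication checkpoint gene CLSPN rose by 0.84 ± 0.13, the kinase gene MTOR by 0.78 ± 0.14 and CTPS1, a CTP synthase gene, by 0.80 ± 0.14 (adjusted p = 0.0047, 0.0086 and 0.00647). The pseudogenes HMGB1P5 and HNRNPA1P48 had log2 fold changes of 0.75 and 0.74 (adjusted p = 0.0187 and 0.0125). These values are uncertain because the pseudogenes may share reads with their parent genes, which was not measured. Both missed the threshold without UDI0051 (adjusted p = 0.056 and 0.0561), as did HMGB1P5 without UDI0052 (adjusted p = 0.0542).

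The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of 10 splits, that by treatment, as many genes were called as in the comparison, 1787 against at most 0 in the others (edgeR). For the list tests this was also 1 of 10, with 16 lists by treatment and at most 12 in the others. The split with 12 lists set UDI0051, UDI0052 and UDI0055 against UDI0053, UDI0054 and UDI0056. Every split other than that by treatment has an uneven number of each treatment on a side. Part of the treatment difference thus stays in it and also widens the spread within sides. Neither the 12 lists nor the 0 genes therefore give a rate of false calls.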
